A study of Homo sapiens and Mus musculus with 27 samples.

How the data were processed

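The series holds 27 RNA-seq libraries of erythroblasts sorted by stage. Human cells came from cultures of cord-blood CD34+ cells and were sorted, per the labels, into 5 stages: proerythroblast, early basophilic, late basophilic, polychromatic and orthochromatic. Mouse cells came from C57BL/6 bone marrow and were sorted into 4 stages: proerythroblast, basophilic, polychromatic and orthochromatic. Each stage has 3 libraries (15 human, 12 mouse), numbered 1 to 3 in the labels. Nothing beyond these labels says that the 3 libraries of a stage come from separate donors or animals, so p-values measure spread between these samples, which may be technical.

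Per the submitters' processing notes, the upstream tools were CASAVA 1.8.2, TopHat 1.3.3, HTSeq and edgeR, the last pair without a version, with builds hg19 for human and mm9 for mouse. The gene annotation and the strand setting are not given in the sources used here. The deposited count tables give raw counts per gene symbol, with 1 column per library. The second kind of table holds the authors' log2 RPKM. In the mouse, column offsets between the log2 RPKM and the counts follow the plain column totals. In human, they imply a library size larger than the total, by 1.74 to 1.92 times at the orthochromatic stage relative to proerythroblast library 1; how that size was set is not given in the sources used here.

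All columns matched a sample (0 unmatched). The human table has 23346 gene rows, of which 96 were dropped before testing: Y-linked genes, XIST and a row that names no gene, which held at most 0.0023 percent of a library's counts. The mouse table has 23283. No library is a copy of another of its stage. The lowest chi-square per degree of freedom was 6.15, for human orthochromatic libraries 2 and 3, which lie closer than any other such pair (39.19 or more).

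Main tests were edgeR quasi-likelihood F-tests on counts (edgeR 4.0.16, R 4.3.3) with TMM scaling, the filterByExpr filter and no block. All libraries of a species entered 1 fit with a mean per stage, over 12860 human and 11120 mouse genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Expression is given as CPM, counts relative to the TMM-scaled library size, as mean ± SD of the 3 libraries of a stage. Compared were each stage with the one before it, orthochromatic with proerythroblast, and all stages at once (F-test with all stage contrasts). The species difference, human log2 fold minus mouse log2 fold, was tested as an interaction in a joint fit with a mean per species and stage. It covered 15481 genes with the same symbol in both species, of which 8580 passed the filter; TMM factors were computed within each species.

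The 32 gene lists were fixed before the data were examined: sort markers; globins; heme synthesis; iron uptake and handling; membrane skeleton; membrane transporters and blood groups; adhesion molecules; erythroid transcription factors; progenitor genes; erythropoietin and KIT signalling; mitophagy and autophagy; DNA replication; mitosis; G1 cyclins and CDK inhibitors; nuclear condensation and enucleation; histone and chromatin modifiers; ribosomal proteins; ribosome biogenesis; translation initiation factors; oxidative phosphorylation; glycolysis; proteasome; ubiquitin conjugation; splicing factors; apoptosis regulators; cholesterol synthesis; antioxidant enzymes; and markers of granulocytes and monocytes, macrophages, megakaryocytes and platelets, lymphocytes, and mast cells, basophils and eosinophils. Each was tested with camera (limma 3.58.1), two-sided, with the preset correlation of 0.01 between genes, and again with an estimated correlation. These p-values were adjusted over all lists and comparisons of a species, and over both species differences together. An adjusted p followed by "estimated" is that with an estimated correlation. At single steps only part of the lists that passed is printed, chosen after the values were seen. Members called are counted adjusted over all genes and adjusted over the list alone.

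Genes are named by a rule. For orthochromatic against proerythroblast these are the 12 largest rises and 12 largest falls among called genes with a mean of at least 20 CPM in the higher group and no overlap between the libraries of the groups. For each adjacent step the same rule takes 5 and 5. From each list it takes up to 3 called members with the largest change and the called member going furthest the other way, in orthochromatic against proerythroblast. For each species difference it takes the 6 largest positive and 6 largest negative. Always named are SLC4A1, ITGA4, CD44, GATA1, GATA2, KLF1, MYC, MYB, KIT, EPOR, TFRC, ALAS2, FOXO3, BNIP3L, BCL11A, CDKN1B, CCND3, E2F2, XPO7 and the adult globin genes. Gene models without a name of their own, small nucleolar RNAs and pseudogenes are not named, and some genes that these rules take are not reported here.

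Composition of the libraries was tested by exact permutation over all partitions into stages: 1401400 in human (smallest possible p = 7.1e-07) and 15400 in the mouse, there also within library number (576 arrangements). Genes detected were counted after thinning every library to 15132836 counts in human and 10508998 in the mouse. Counting intervals are 95 percent; a group with no counts is given a floor of 3 counts, and both cover counting error only. Total counts in units of M (mega) ran from 15.1 to 152.6 in human and from 10.5 to 66.5 in the mouse, with library 1 of each stage the deepest.

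Whether equal library numbers pair the stages was checked by correlating deviations from the stage means. In human, libraries with equal numbers correlated at 0.67 to 0.73 between proerythroblast and early basophilic, 0.68 to 0.81 between early and late basophilic, 0.34 to 0.5 between late basophilic and polychromatic, and 0.11 to 0.53 between polychromatic and orthochromatic. At that last step polychromatic 2 correlated with orthochromatic 3 at 0.282, above the 0.106 of the pair numbered 3, so calls there with the block only rest on a weak pairing. In the mouse the adjacent steps gave 0.65 to 0.83, 0.69 to 0.84 and 0.71 to 0.83, and orthochromatic with proerythroblast 0.71 to 0.84. These were taken as paired, as every correlation was over 0.1, on the data alone; human orthochromatic with proerythroblast was not. A fit with library number as a block is given beside a result where it changes the call or moves a count of calls by over 1.5 times.

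Alternatives chosen beforehand were RLE size factors, no filter on low counts, DESeq2 1.42.0, the block, globin genes left out of library sizes and TMM, only the 6 libraries of the compared stages, limma on log2 RPKM with 1 added on the RPKM scale, and each library left out in turn; the species difference also had limma-voom with library weights. Added after seeing the data were plain totals with no scaling factor and permuting mouse composition within library number. So was leaving out all libraries numbered 1 or, in the mouse, 3 (never 2). Calls lost there may reflect fewer libraries. The fits were tested on simulated data: of 100 genes given a 4-fold change, 93 percent were called in human orthochromatic against polychromatic, 71 percent in the mouse, and 68 percent for the species difference in orthochromatic against proerythroblast. A 2-fold change was called in 33, 12 and 12 percent.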

Results

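Globin transcripts took a growing share of the counts in both species. In human the globin genes held 1.11 ± 0.194 percent of counts in proerythroblasts, 1.69 ± 0.5 in early basophilic, 3.21 ± 1.1 in late basophilic, 10.6 ± 0.346 in polychromatic and 21 ± 1.49 in orthochromatic cells (mean ± SD, n = 3 libraries per stage, exact permutation p = 7.1e-07, the smallest possible). In the mouse they held 0.665 ± 0.169, 3.45 ± 0.648, 3.54 ± 0.534 and 6.39 ± 1.59 percent from proerythroblast to orthochromatic (n = 3 per stage; exact permutation p = 0.00065). At equal depth, 14500.3 ± 158 genes were detected in human proerythroblasts and 13576 ± 168 in orthochromatic cells (exact permutation p = 0.00047, n = 3 per stage), against 12362.7 ± 522 and 11272.3 ± 533 in the mouse (exact permutation p = 0.22, but 0.0069 permuted within library number, n = 3 per stage). Mouse alpha-globin genes Hba-a1 and Hba-a2 are near-identical copies that held almost no counts, so the mouse globin share is mostly that of the beta-globin row Beta-s.

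**Figure D1:**
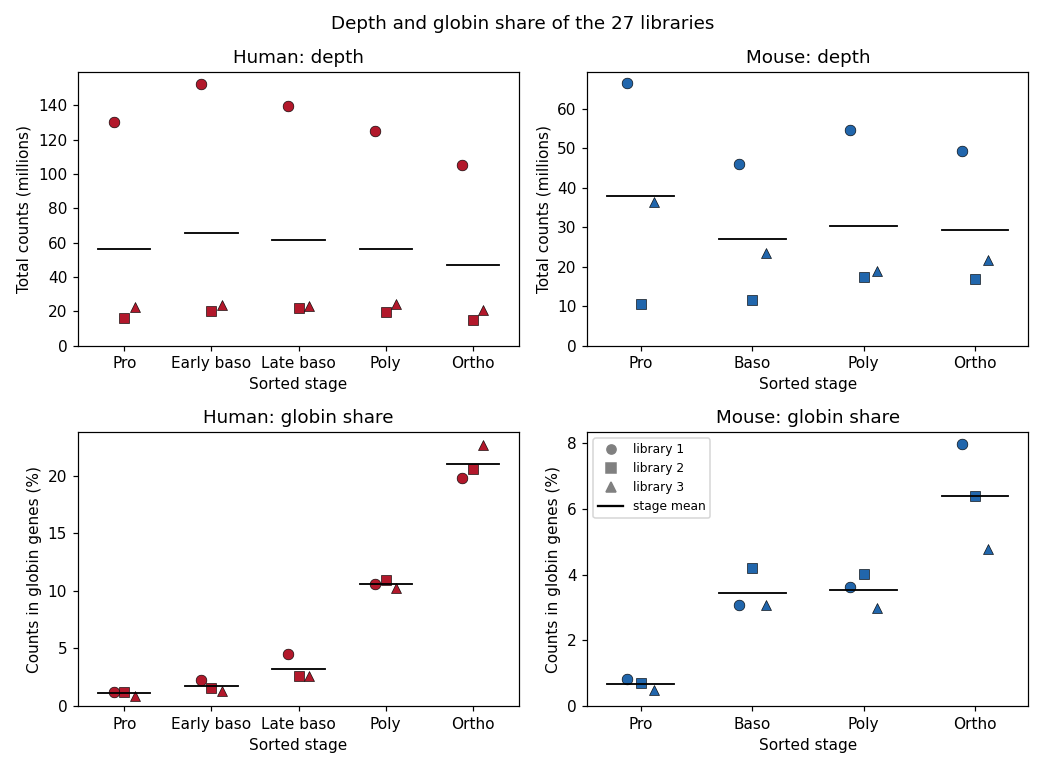
Total counts (M) (above) and globin genes as percent of counts (below) for each library by stage, human left and mouse right. Markers show library numbers and black lines the stage means (n = 3 per stage). Libraries numbered 1 are the deepest (105.1 to 152.6 M in human, 46.1 to 66.5 M in the mouse).

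Library number went with gene groups other than the erythroid ones in the mouse. Granulocyte and monocyte markers held 0.234 to 0.463 percent of counts in the mouse libraries numbered 1 and at most 0.019 percent in the others. Ribosomal protein genes held 6.59, 1.62, 1.42 and 0.921 percent of counts in the mouse libraries numbered 3, from proerythroblast to orthochromatic, and at most 1.53 percent in the others.

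With TMM, SLC4A1 and ALAS2 read higher at each human stage, but not every step passed. SLC4A1, the human sort marker band 3, read 1051 ± 123, 3724 ± 1406, 10720 ± 3305, 31950 ± 3023 and 46290 ± 2659 CPM from proerythroblast to orthochromatic (mean ± SD, n = 3 per stage, here and in the values that follow). ALAS2, which makes the first heme precursor, read 736 ± 4.65, 1332 ± 293, 2756 ± 830, 11560 ± 1503 and 36040 ± 3207 CPM. The adhesion receptor gene CD44 read 68.7 ± 10.4, 52.5 ± 0.639, 41.7 ± 5.77, 199 ± 49.5 and 416 ± 44.8 CPM, against 457 ± 112 to 53.5 ± 36 CPM from first to last stage for the integrin gene ITGA4. Over the same stages KLF1 went from 450 ± 69.3 to 3418 ± 400 CPM, FOXO3 from 51.5 ± 1.76 to 5304 ± 1263, XPO7 from 139 ± 13.6 to 12110 ± 3057 and MYC from 403 ± 25 to 22.9 ± 13.4.

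Between the first and last human stage, GATA1 went from 247 ± 25.9 to 842 ± 128 CPM, E2F2 from 24.3 ± 13.7 to 3907 ± 1135 and the mitophagy receptor gene BNIP3L from 233 ± 14.3 to 6834 ± 2361. The CDK inhibitor gene CDKN1B went from 60.7 ± 11.3 to 1291 ± 283 CPM, EPOR from 208 ± 24.9 to 781 ± 36.5 and GATA2 from 14.2 ± 7.81 to 41.9 ± 5.23. KIT went from 208 ± 30.4 to 1.72 ± 0.887 CPM and MYB from 310 ± 65.9 to 2.52 ± 1.98. With TMM, TFRC peaked at polychromatic (6669 ± 785, 19860 ± 3962 and 9629 ± 857 CPM), and BCL11A there (44.1 ± 14.5, 90.8 ± 9.24 and 14.9 ± 0.498 CPM) or at late basophilic. CCND3 peaked at late basophilic (92 ± 15.2, 663 ± 154 and 110.5 ± 10.9 CPM).

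Of the human globin genes, HBB went from 2666 ± 1165 to 232800 ± 76110 CPM and HBD from 299 ± 91.3 to 2452 ± 694. The fetal gene HBG1 went from 490 ± 271 to 49250 ± 2577 CPM and HBG2 from 2652 ± 516 to 172700 ± 9970. The alpha gene HBA1 went from 296 ± 0.816 to 45690 ± 14820 CPM and HBA2 from 211 ± 19 to 67040 ± 7601. The split of counts within each of these pairs of near-identical genes is uncertain.

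**Figure D2:**
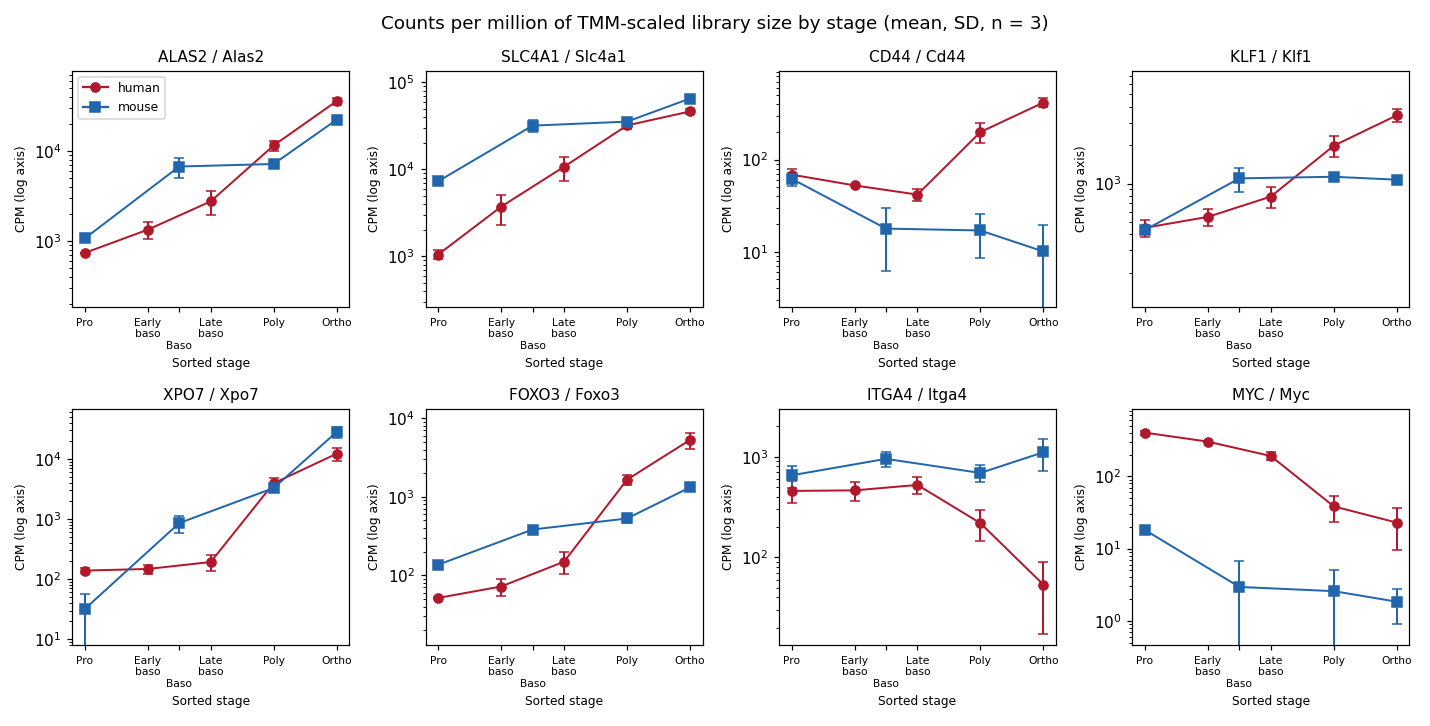
Mean CPM with SD (log axis; n = 3 libraries per stage) over the sorted stages for 8 genes, human in red circles and mouse in blue squares; bars whose lower end reaches 0 run off the axis. CD44 goes from 68.7 to 416 CPM in human and from 62 to 10.1 CPM in the mouse.

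In the mouse Slc4a1 and Alas2 rose mostly between proerythroblast and basophilic and between polychromatic and orthochromatic. Through these 4 stages Slc4a1 read 7300 ± 584, 31780 ± 5195, 35350 ± 1517 and 65110 ± 2734 CPM, and Alas2 1067 ± 75, 6736 ± 1714, 7187 ± 465 and 22360 ± 2077 CPM. Xpo7 read 32 ± 24.5, 854 ± 276, 3265 ± 460 and 27790 ± 5760 CPM, and Cd44 62 ± 10.2, 17.8 ± 11.7, 17 ± 8.37 and 10.1 ± 9.21 CPM. Between the first and last stage Itga4 went from 653 ± 164 to 1108 ± 383 CPM, Foxo3 from 136 ± 17.7 to 1317 ± 48.6, Klf1 from 433 ± 20 to 1072 ± 25.1 and Myc from 18.1 ± 0.917 to 1.84 ± 0.944.

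Tfrc went from 2268 ± 409 to 9042 ± 2740 CPM, E2f2 from 799 ± 65.3 to 5661 ± 553 and Gata1 from 285 ± 17.3 to 559 ± 18.2. Epor went from 186 ± 12 to 576 ± 33.5 CPM, Bnip3l from 148 ± 68.5 to 3636 ± 2187 and Cdkn1b from 46 ± 13 to 1275 ± 535. Ccnd3 went from 863 ± 170 to 384 ± 51.3 CPM, Bcl11a from 44.3 ± 2.76 to 2.33 ± 2.67, Kit from 10.2 ± 5.29 to 0.935 ± 1.53, Myb from 23.9 ± 11.2 to 7.18 ± 2.62 and Gata2 from 1.4 ± 1.35 to 0.721 ± 1.06. The beta-globin row Beta-s went from 3550 ± 532 to 104800 ± 16360 CPM, Hbb-b1 from 81 ± 72.8 to 1072 ± 326 and Hbb-b2 from 5.18 ± 0.363 to 108 ± 3.3. Hba-a1 (0.0463 ± 0.0435 to 6.45 ± 6.99 CPM) and Hba-a2 (1.2 ± 2.07 to 8.63 ± 7.84 CPM) are uncertain, being copies that share their reads.

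From proerythroblast to early basophilic in human, few genes were called. The largest rises were PAQR9 (4.01 ± 1.89 to 30.1 ± 18 CPM, log2 fold 2.89), TNS1 (24.9 ± 0.77 to 170 ± 101, 2.77), the water channel AQP3 (3.57 ± 0.677 to 21.2 ± 4.07, 2.58), the alpha-like globin HBM (18.8 ± 2.89 to 92.5 ± 12.7, 2.3) and the glycine transporter SLC6A9 (35.8 ± 5.98 to 140 ± 72.8, 1.97), with n = 3 per stage and adjusted p = 0.018, 0.01, 5.5e-05, 0.0041 and 0.031. SLC4A1 (log2 fold 1.82, adjusted p = 0.018) and CCND3 (1.47, adjusted p = 0.031) also rose. HMGCS1, of cholesterol synthesis, fell from 437 ± 44.4 to 226 ± 31.3 CPM (adjusted p = 0.026). In all, 21 genes rose and 3 fell of 12860 (150 and 136 with the block, 1 and 0 without proerythroblast library 1). Of the always-named genes the block added KIT (log2 fold -1.05, adjusted p = 0.12 without and 0.014 with it), HBA1 (0.14 and 0.033), HBA2 (0.12 and 0.018) and E2F2 (0.11 and 0.022). The other always-named genes did not pass, from MYB (-0.7, adjusted p = 0.71) to ALAS2 (0.86, 0.21).

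Mitosis genes shifted up together at this first step (median log2 fold 0.57 over 45 genes, camera adjusted p = 1.5e-12 and 0.42 estimated, meaning with an estimated instead of the preset correlation). None of them passed alone (0 by edgeR, 0 adjusted over the list alone, 0 with the block). At an unadjusted p under 0.05 were 975 genes. Of the genes named here only AQP3 passed under every other setting and with any single library left out.

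From early to late basophilic in human TNS1, PAQR9 and HBM went on rising and KIT fell. SLC6A19, a transporter of neutral amino acids, rose from 3.81 ± 2.62 to 29.8 ± 10.4 CPM (log2 fold 2.93, adjusted p = 0.019), TNS1 from 170 ± 101 to 787 ± 339 (2.21, 0.0096), PAQR9 from 30.1 ± 18 to 129 ± 28.8 (2.09, 0.018), HBM from 92.5 ± 12.7 to 395 ± 56.2 (2.09, 0.0053) and the interferon-induced RSAD2 from 6.29 ± 3.68 to 27.1 ± 18.8 (2.09, adjusted p = 0.023). Among the largest falls were DDN (70.4 ± 28.8 to 15.8 ± 5.64 CPM, adjusted p = 0.014), KIT (log2 fold -1.91, 0.0053), SLC10A4 (24.2 ± 13.6 to 6.62 ± 3.96, 0.044) and MGST1 (22.2 ± 2.45 to 6.29 ± 2.1, 0.016). SLC4A1 (log2 fold 1.53, adjusted p = 0.014), ALAS2 (1.05, 0.028), FOXO3 (1.05, 0.032), CDKN1B (1.1, 0.014), CCND3 (1.38, 0.014), HBA1 (1.32, 0.025) and HBA2 (1.67, 0.033) rose. Of the always-named genes the block added KLF1 (adjusted p = 0.16 without and 0.037 with it), MYB (0.091 and 0.0055), EPOR (0.081 and 0.0073), BCL11A (0.16 and 0.044), E2F2 (0.053 and 0.01) and HBG2 (0.095 and 0.014). The other always-named ones did not pass, from MYC (-0.66, adjusted p = 0.27) to HBB (1.18, 0.17).

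In all, 319 genes rose and 257 fell at this step (1273 and 1103 with the block, 187 and 608 under plain library totals, 11 and 14 without early basophilic library 3). Ribosome biogenesis genes shifted down (11 of 48 fell, 27 adjusted over the list alone, 29 with the block, median -0.51, adjusted p = 3.4e-16 and 0.032 estimated). Of the genes named here only HBM and KIT passed with any single library left out.

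From late basophilic to polychromatic in human, many genes changed. IFIT1B rose from 0.337 ± 0.0269 to 123 ± 70.5 CPM (log2 fold 8.5), the ERK phosphatase gene DUSP5 from 0.102 ± 0.0883 to 42.5 ± 19.9 (8.41), the netrin receptor gene UNC5B from 0.147 ± 0.146 to 58.5 ± 55.4 (8.21), the hypoxia factor EPAS1 from 0.419 ± 0.312 to 111 ± 21.4 (7.79) and the actin-binding ABLIM1 from 0.57 ± 0.0916 to 114 ± 107 (7.61), with adjusted p from 1.8e-07 to 4.4e-05. FAM178B fell from 143 ± 95.6 to 0.577 ± 0.54 CPM, the adhesion molecule EPCAM from 20.7 ± 8.09 to 0.132 ± 0.0794, the keratin KRT13 from 53.5 ± 11.4 to 0.317 ± 0.114, S100A4 from 155 ± 43.4 to 1.07 ± 0.132 and ACSBG1 from 48.3 ± 14.5 to 0.438 ± 0.24 (adjusted p from 3.6e-08 to 2.4e-05). XPO7 (log2 fold 4.35, adjusted p = 6.6e-08), FOXO3 (3.47, 1.8e-07), BNIP3L (3.26, 3.5e-07), CD44 (2.25, 3.4e-07) and ALAS2 (2.07, 6e-06) rose. So did SLC4A1 (1.58), KLF1 (1.32), CDKN1B (1.73), E2F2 (1.92), EPOR (1.04, -0.01 with limma on log2 RPKM), TFRC (0.72, adjusted p = 0.021), GATA1 (0.51, adjusted p = 0.024), HBA1 (2.48), HBA2 (2.63), HBB (2.74), HBD (1.25), HBG1 (2.41) and HBG2 (2.17). MYB (log2 fold -5.76, adjusted p = 1.8e-07), KIT (-5.58, 1.6e-08), MYC (-2.31, 4.8e-05), ITGA4 (-1.26, 0.034) and CCND3 (-0.65, 0.037) fell. BCL11A (0.2, adjusted p = 0.38) and GATA2 (0.65, adjusted p = 0.34; 0.046 with the block) did not pass. Under plain totals GATA1 (-0.27) and TFRC (-0.06) had the opposite sign.

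Ribosome biogenesis fell as a list at this step (43 of 48 fell and 1 rose, median -1.91, adjusted p = 1.1e-23 and 0.023 estimated). In all, 3363 genes rose and 4091 fell, against 1526 and 7198 under plain totals.

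From polychromatic to orthochromatic in human, DNA replication and mitosis genes fell almost as whole lists. ANKRD33 rose from 0.0531 ± 0.053 to 27.6 ± 6.67 CPM, HMP19 from 0.107 ± 0.0668 to 29.5 ± 12.5, the GTPase gene RRAD from 0.179 ± 0.0748 to 35.7 ± 10.7, the Notch-regulated NRARP from 0.797 ± 0.698 to 94.8 ± 62.1 and HMOX1, which degrades heme, from 26 ± 8.68 to 3359 ± 210 CPM (log2 fold 8.92, 8.6, 7.84, 7.08 and 7.02; adjusted p from 5.7e-08 to 9.9e-06). Falling most were APOBEC3B (24.7 ± 10.3 to 2.44 ± 0.387 CPM), the recombination gene RAD54L (56 ± 5.12 to 6.14 ± 3.86), CDCA4 (132 ± 13.5 to 15.1 ± 8.36), the microtubule regulator STMN1 (475 ± 124 to 52.7 ± 10.6) and ARHGAP33 (72.1 ± 27.6 to 8.65 ± 4.81), with adjusted p from 1.8e-07 to 0.00015. BNIP3L (log2 fold 2.03, adjusted p = 1.8e-05), FOXO3 (1.68, 6e-05), ALAS2 (1.64, 4.8e-05), XPO7 (1.63, 0.00012), CDKN1B (1.17, 0.00023) and CD44 (1.06, 2e-04) rose. So did GATA2 (log2 fold 1.58, adjusted p = 0.029), KIT (1.71, 0.00049), KLF1 (0.79, 0.0044), GATA1 (0.66, 0.0062), HBA1 (2.24), HBA2 (2.23), HBB (1.85, 0.0048), HBG1 (2.43) and HBG2 (2.26). KLF1 (-0.27) and GATA1 (-0.4) had the opposite sign under plain totals, and with limma CDKN1B (-0.41) and CD44 (-0.44) did. BCL11A (log2 fold -2.61, adjusted p = 4.9e-07), ITGA4 (-2.05, 0.0028), CCND3 (-1.94, 2.3e-05) and TFRC (-1.04, 0.0024) fell. SLC4A1 (log2 fold 0.53, adjusted p = 0.11) did not pass; MYC (-0.72, 0.079), E2F2 (1.16, 0.062) and HBD (0.8, 0.09) passed with the block only (0.028, 0.022 and 0.032), where pairing is weak.

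DNA replication (40 of 45 fell and 0 rose, median -2.2, adjusted p = 9.6e-17 and 0.28 estimated) and mitosis (44 of 45 fell and 0 rose, median -2.22, adjusted p = 1.1e-13 and 0.39 estimated) had the lowest p at this last human step. In all, 3585 genes rose and 3607 fell, against 1305 and 7131 under plain totals.

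Over the whole human course, from proerythroblast to orthochromatic, 10086 of 12860 genes changed: 4512 rose and 5574 fell, against 1683 and 9526 under plain totals. Values after "plain" are those under plain totals. The median log2 fold of all genes was -0.34 with TMM and -2.491 with plain totals. The epithelial factor ELF3 rose 43400-fold by pooled counts (95 percent counting interval 7790 to 1710000) to 262 ± 139 CPM. OSR2, SFRP2, the phosphodiesterase gene PDE2A, HMP19 and ANKRD33 had 0 counts in proerythroblasts and rose at least 3670-, 2160-, 2490-, 1890- and 2120-fold, to 79.7 ± 52.7, 47.5 ± 31.4, 34.6 ± 10.2, 29.5 ± 12.5 and 27.6 ± 6.67 CPM. RUNDC3A rose from 0.486 ± 0.0974 to 4454 ± 495 CPM, TCP11L2 from 0.319 ± 0.215 to 2651 ± 530, ASAP3 from 0.00772 ± 0.0134 to 167 ± 38.6, TMCC2 from 3.64 ± 0.906 to 29330 ± 10010, KRT1 from 0.0216 ± 0.0374 to 350 ± 149 and IFIT1B from 0.218 ± 0.0171 to 1456 ± 812 (adjusted p of these 12 from 2.3e-10 to 4.8e-06).

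Among the largest human falls were FAM178B (403 ± 201 to 1.17 ± 1.03 CPM), EPCAM (59.5 ± 12.7 to 0.363 ± 0.513), the noncoding UCA1 (65.6 ± 6.12 to 0.389 ± 0.306), APBB1IP (40.9 ± 3.44 to 0.227 ± 0.302) and MOB3B (63.1 ± 18.7 to 0.609 ± 0.464). Next came SLC16A9 (302 ± 82.7 to 2.43 ± 2.15 CPM), ACSBG1 (75.8 ± 19.2 to 0.807 ± 0.628), OAF (22.4 ± 4.78 to 0.291 ± 0.274), ZNF618 (29 ± 8.46 to 0.279 ± 0.248), SEMA4C (75.5 ± 7.52 to 0.557 ± 0.35) and PPM1H (47 ± 46.5 to 0.252 ± 0.218), all with adjusted p from 9.8e-10 to 0.00015. Of the always-named genes, E2F2 (log2 fold 7.33, adjusted p = 1e-07), FOXO3 (6.69, 3.2e-10), XPO7 (6.45, 5.2e-10), ALAS2 (5.61, 5.2e-10), SLC4A1 (5.46, 2.2e-09), BNIP3L (4.87, 2.3e-09) and CDKN1B (4.41, 6.6e-10) rose most, then KLF1 (2.92) and CD44 (2.6), both with the opposite sign with limma on log2 RPKM (-0.12 and -0.4). EPOR (1.91), GATA1 (1.77) and GATA2 (1.55, adjusted p = 0.022) rose too, but had the opposite sign under plain totals (-0.26, -0.42 and -0.6). MYB (log2 fold -7.25, adjusted p = 6.2e-09), KIT (-6.83, 3e-10), MYC (-4.1, 1.2e-07), ITGA4 (-3.12, 6.1e-05) and BCL11A (-1.56, 6.2e-06) fell. TFRC (0.53, adjusted p = 0.061) and CCND3 (0.26, adjusted p = 0.34) did not pass.

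Erythroid lists rose over the human course. All 10 globins rose (median log2 fold 6.29, adjusted p = 1.1e-06 and 0.16 estimated), embryonic HBE1 most (9.59) ahead of HBA2 (8.31), HBA1 (7.27), HBG1 (6.65), HBB (6.45), HBG2 (6.03) and HBD (3.04, limma -0.01). Transporters and blood groups (22 of 30 rose and 2 fell, median 3.09, adjusted p = 2.7e-06 and 0.3 estimated) were led by the urea transporter SLC14A1 (8.38), BCAM (6.24) and the glucose transporter SLC2A1 (6.21). The channel PIEZO1 fell (-2.22). Erythroid transcription factors (21 of 30 rose and 7 fell, median 3.07, adjusted p = 2.9e-06 and 0.28 estimated) included STAT5A (-4.42) among those that fell. The membrane skeleton list (14 of 19 rose and 3 fell, median 1.63, plain -0.56, adjusted p = 0.00011 and 0.28 estimated) held EPB49 (5.48), EPB41 (5.43) and SPTAN1 (4.99). ADD2 fell (-2.8). Heme synthesis (11 of 15 rose and 1 fell, median 1.37, plain -0.82, adjusted p = 0.0059 and 0.54 estimated) held TSPO2 (5.81) and the porphyrin transporter ABCB6 (5.61). TMEM14C fell (-2.23). Iron uptake and handling (13 of 21 rose and 6 fell, median 1.38, plain -0.75, adjusted p = 0.0048 and 0.21 estimated) held the ferritin receptor NCOA4 (6.57), the mitochondrial iron importer SLC25A37 (5.62) and ISCU (5.52). The heme exporter FLVCR1 fell (-4.4). Of the 4 sort markers 3 rose and 1 fell (median 2.88, adjusted p = 0.081).

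Clearance, signalling and antioxidant lists rose with them. Mitophagy and autophagy (27 of 35 rose and 5 fell, median log2 fold 3.08, adjusted p = 4.7e-10 and 0.16 estimated) was led by GABARAPL1 (8.21), ATG14 (6.36) and PINK1 (6.09). ATG4C fell (-3.6). Ubiquitin conjugation (36 of 50 rose and 7 fell, median 1.86, plain -0.37, adjusted p = 1.4e-08 and 0.16 estimated) held UBE2H (7.94), FBXO30 (7.12) and UBXN6 (6.29). UBE2E1 fell (-1.76). G1 cyclins and CDK inhibitors (15 of 24 rose and 3 fell, median 1.29, plain -0.93, adjusted p = 0.0045 and 0.28 estimated) held CDKN2B (10.69), CDKN2D (8.37) and CDKN1A (7.25). CDK2 fell (-2.94). Erythropoietin and KIT signalling (18 of 24 rose and 6 fell, median 1.93, plain -0.19, adjusted p = 0.0037 and 0.39 estimated) held the survival gene BCL2L1 (8.49), PIM1 (5.49) and PIM2 (5.33). LYN fell (-2.24). Antioxidant enzymes (20 of 27 rose and 4 fell, median 1.58, plain -0.62, adjusted p = 0.0021 and 0.28 estimated) held HMOX1 (11.54), GCLC (4.88) and GPX1 (4.27). PRDX3 fell (-3.16). Megakaryocyte and platelet markers (14 of 17 rose, 15 adjusted over the list alone, median 4.01, adjusted p = 0.009 and 0.58 estimated) held PPBP (6.87), THBS1 (6.23) and TUBB1 (4.03).

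Growth lists fell over the human course. Ribosome biogenesis (41 of 48 fell and 4 rose, median log2 fold -2.45, adjusted p = 3e-11 and 0.11 estimated) was led by POLR1A (-4.19), RRP9 (-4.12) and DDX10 (-4.07). SBDS rose (1.42, plain -0.78). DNA replication (40 of 45 fell and 2 rose, 41 and 2 adjusted over the list alone, median -2.8, adjusted p = 1.6e-08 and 0.43 estimated) was led by MCM6 (-4.73), MCM3 (-4.63) and RFC2 (-4.41). RFC3 rose (1.47, plain -0.71). Ribosomal proteins (56 of 79 fell and 7 rose, median -1.23, adjusted p = 0.00045 and 0.71 estimated) held RPL22L1 (-3.98), RPL10A (-3.55) and RPL13A (-2.88). RPS27L rose (2.37, limma -0.64). Progenitor genes (13 of 22 fell and 7 rose, median -3.04, adjusted p = 0.015 and 0.17 estimated) had the early response gene EGR1 (6.34) going the other way. In oxidative phosphorylation (36 of 65 fell and 18 rose, median -0.64, adjusted p = 0.039 and 0.68 estimated) the ATP synthase genes ATP5G1 (-4.18), ATP5G2 (-3.82) and ATP5G3 (-3.6) fell and ATP5E rose (1.94, plain -0.23).

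The remaining human lists did not shift as a whole over the course. Mitosis (16 of 45 fell and 4 rose, 15 and 4 adjusted over the list alone, median log2 fold -0.49, adjusted p = 0.44) held MAD2L1 (-2.59), CDC20 (-2.4) and BUB1B (-1.99). CDC25B rose (1.98, plain -0.21). Glycolysis (13 of 21 fell and 5 rose, median -1.33, adjusted p = 0.21) held BPGM (8.04), which makes 2,3-bisphosphoglycerate, against PKLR (-5.35) and LDHB (-5.33). Splicing factors (31 of 55 fell and 11 rose, median -0.84, adjusted p = 0.066) held SNRPF (-3.96) and SNRPD1 (-3.93), against MBNL2 (5.4); proteasome (22 of 43 rose and 10 fell, median 0.43, plain -1.75, adjusted p = 0.14) held PSME4 (4.43) and PSMF1 (3.08). PSMG1 fell (-3.79). Translation initiation factors (15 of 41 rose and 20 fell, median -0.55 but mean 0.03, adjusted p = 0.91) held EIF2AK1 (4.3), PPP1R15A (4.24) and EIF5 (4.05). EIF2B3 fell (-3.03). Histone and chromatin modifiers (20 of 45 rose and 24 fell, median -0.61 and mean -0.05, though the test pointed up, adjusted p = 0.55) held KDM6B (6.08), EP300 (5.07) and CREBBP (4.21). HDAC7 fell (-3.88). Nuclear condensation and enucleation (14 of 33 rose and 12 fell, median 0.16, plain -2.03, adjusted p = 0.43) held HDAC5 (6.95), TRIM58 (6.86) and TOP1 (4.26). KAT2A fell (-3.31). Apoptosis regulators (14 of 27 rose and 10 fell, median 0.51, plain -1.65, adjusted p = 0.16) held BIRC3 (7.98), BIRC2 (5.33) and FAS (5.1). CASP6 fell (-4.51).

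Cholesterol synthesis in human (6 of 22 rose and 7 fell, median log2 fold 0.07, plain -2.13, but mean -0.01, adjusted p = 0.98) held MSMO1 (3.69) and TM7SF2 (3.32). EBP fell (-3.06). Adhesion molecules (6 of 16 rose and 5 fell, median 0.26, plain -1.9, adjusted p = 0.79) held ITGB3 (4.56) and SELPLG (2.74, limma -0.4). CD81 fell (-2.72). Of markers of other cells, those of granulocytes and monocytes (12 of 18 rose and 1 fell, 11 and 1 adjusted over the list alone, median 2.59, adjusted p = 0.28) held CYBB (1.44, plain -0.76, under which 0 of the list rose). Macrophage markers (5 of 9 rose and 2 fell, 6 and 2 adjusted over the list alone, median 2.77, adjusted p = 0.33) held MERTK (8.8) and CTSB (4.89). APOE fell (-6.53). Lymphocyte markers (2 of 7 rose and 3 fell, 2 and 4 adjusted over the list alone, median -1.59 but mean 0.1, adjusted p = 0.79) and those of mast cells, basophils and eosinophils (1 of 8 rose and 3 fell, median -0.36, adjusted p = 0.88; SRGN 1.77, plain -0.32) stayed mixed. Adjusted over the list alone, counts of the human lists over the whole course were otherwise the same.

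**Figure D3:**
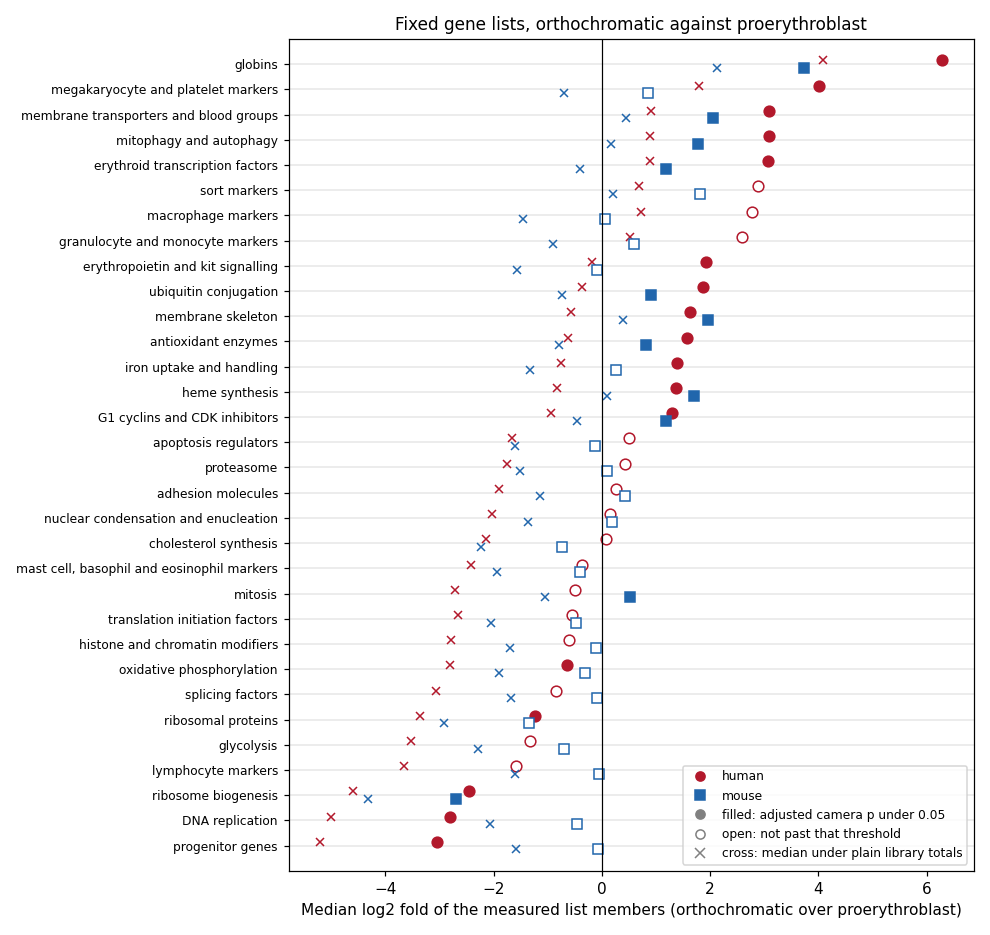
Median log2 fold of each gene list, orthochromatic against proerythroblast, human in red circles and mouse in blue squares, each over the 3 libraries per stage; filled markers have camera adjusted p under 0.05 with the preset correlation and crosses give the median under plain totals. Globins are highest (6.29 and 3.74) and crosses lie lower.

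From proerythroblast to basophilic in the mouse, mitosis genes rose as a list. Hist1h2bc rose from 3.77 ± 0.115 to 105 ± 60.4 CPM (log2 fold 4.8; a histone gene with near-identical copies, so uncertain), Xpo7 by a log2 fold of 4.74, the cyclin gene Ccng2 from 3.67 ± 0.21 to 92 ± 50.4 (4.64), Sowaha from 17.6 ± 2.06 to 392 ± 163 (4.47) and Tcp11l2 from 4.42 ± 4.09 to 74.1 ± 25.9 (4.05), with adjusted p from 3.6e-05 to 0.00083. Hmgn1 fell from 33.9 ± 26.1 to 3.08 ± 1.74 CPM (adjusted p = 0.0044), the endoglin gene Eng from 43.3 ± 9.14 to 4.02 ± 5.87 (0.039), Utp20 from 26.4 ± 3.67 to 2.64 ± 3.14 (0.048) and the mitochondrial chaperone genes Hspe1 from 22.9 ± 11.8 to 2.64 ± 1.96 (0.013) and Hspd1 from 87.6 ± 57.8 to 10.3 ± 5.86 (0.0081). None of these falls passed without the libraries numbered 3 (adjusted p = 0.088 or more). Cdkn1b (log2 fold 3.35, adjusted p = 0.0011), Beta-s (3.3, 4.2e-05), Hbb-b2 (2.96, 0.00014), Alas2 (2.66, 2.6e-05), Slc4a1 (2.12, 3.5e-05), E2f2 (1.68, 6.7e-05), Epor (1.58, 0.00016), Foxo3 (1.49, 4.2e-05) and Klf1 (1.34, 0.00015) rose. Bnip3l (log2 fold 2.21, adjusted p = 0.032), Tfrc (1.36, 0.005), Gata1 (0.96, 0.00084), Hbb-b1 (2.28, 0.019) and Hba-a1 (4.83, 0.035) rose, and Bcl11a fell (-2.58, 0.043), but not without the libraries numbered 3. Passing with the block only were Cd44 (-1.79, adjusted p = 0.053 without and 0.00019 with it), Myc (-2.59, 0.052 and 5e-04), Ccnd3 (-0.46, 0.079 and 0.01), Itga4 (0.54, 0.17 and 0.0018), Myb (-1.61, 0.26 and 0.0031) and Kit (-1.81, 0.35 and 0.0023). Gata2 (-1.33, adjusted p = 0.48) and Hba-a2 (0.49, adjusted p = 0.91) did not pass.

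Mitosis had the lowest p at this mouse step (44 of 45 rose, median log2 fold 1.7, adjusted p = 2.4e-20 and 0.48 estimated). Ribosomal proteins passed with the block (6 of 79 fell without, 5 adjusted over the list alone, 68 with it, median -1.07, adjusted p = 0.093 and 8.5e-11) and without the libraries numbered 3 (median -0.75, adjusted p = 2.2e-07). In all, 2266 genes rose and 2113 fell (3084 and 3921 with the block; 925 falls without basophilic library 2). Under plain totals 962 rose and 4887 fell, and without the libraries numbered 3 the counts were 911 and 20.

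Between basophilic and polychromatic in the mouse few genes changed: 85 rose and 16 fell of 11120 (522 and 322 with the block; 36 and 4 under plain totals; 0 and 0 without basophilic library 2). Klf10, a TGF-beta-inducible factor, rose from 13.3 ± 1.53 to 54.9 ± 12 CPM (log2 fold 2.05, adjusted p = 0.023), Khnyn from 16.5 ± 2.12 to 54.3 ± 1.94 (1.72, 0.025), the interferon-induced Oasl2 from 10.1 ± 2.25 to 32.4 ± 9.08 (1.67, 0.013), the cell cycle repressor E2f7 from 30.3 ± 5.19 to 95.9 ± 3.99 (1.66, 0.011) and Gna11 from 7.33 ± 0.774 to 23 ± 2.55 (1.65, adjusted p = 0.025). Cited4 fell from 21.4 ± 3.4 to 8.3 ± 1.17 CPM (adjusted p = 0.0086), the scaffold gene Iqgap2 from 186 ± 5.78 to 96.8 ± 13.2 (0.026), Gipc1 from 28.7 ± 5.86 to 15.3 ± 0.147 (0.03), Muted from 33.8 ± 4.39 to 18.4 ± 3.74 (0.035) and Gpr108 from 20.9 ± 1.76 to 11.6 ± 1.65 (0.026). None of the always-named genes passed; Xpo7 (1.93, adjusted p = 0.094 without and 0.031 with the block), Foxo3 (0.47, 0.12 and 0.042) and Itga4 (-0.47, 0.61 and 0.036) did with the block. The others ran from Bcl11a (-1.05, adjusted p = 0.77) to Hba-a2 (0.93, 1). Ribosomal proteins passed with the block only (0 of 79 fell without and 12 with it, median -0.28, adjusted p = 0.088 and 6.9e-15). At an unadjusted p under 0.05 were 1450 genes. No gene passed with only the 6 libraries of this step or without the libraries numbered 3, while 1442 rose and 1336 fell without those numbered 1.

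From polychromatic to orthochromatic in the mouse, the mitosis list fell and the mitophagy list rose at the preset correlation only. Bpgm rose from 956 ± 123 to 7350 ± 1196 CPM (log2 fold 2.94, adjusted p = 7.2e-05). Zfp874a rose from 27.8 ± 11.5 to 239 ± 110 CPM (log2 fold 3.11, adjusted p = 0.004), Xpo7 from 3265 ± 460 to 27790 ± 5760 (3.09, 0.0026), Tcp11l2 from 313 ± 51.9 to 2644 ± 677 (3.08, 0.0062) and Sdr39u1 from 11.8 ± 2.08 to 90.3 ± 42.7 (2.94, adjusted p = 0.0061). Gas2l3 fell from 97 ± 5.6 to 26.3 ± 4 CPM, the helicase gene Pif1 from 219 ± 29.2 to 61.5 ± 31.5, Hyls1 from 56 ± 2.22 to 15.8 ± 3.47, the spindle gene Fam83d from 93.5 ± 1.94 to 26.8 ± 12.8 and the mitotic phosphatase gene Cdc25c from 123 ± 9.71 to 35.5 ± 10.5 (adjusted p from 0.0042 to 0.0088). Foxo3 (log2 fold 1.32, adjusted p = 0.00015), Alas2 (1.64, 0.00047), Beta-s (1.51, 0.0042), Hbb-b2 (1.29, 0.018), E2f2 (0.91, 0.0038) and Slc4a1 (0.88, 0.0063) rose. Of all these only Bpgm and Foxo3 passed without the libraries numbered 3. Passing with the block only were Bnip3l (2.25, adjusted p = 0.061 without and 6.7e-06 with it), Cdkn1b (1.65, 0.053 and 3.2e-05), Tfrc (0.84, 0.082 and 2e-04), Itga4 (0.68, 0.18 and 0.002), Hbb-b1 (1.27, 0.25 and 0.0011), Hba-a1 (2.43, 0.32 and 0.0099), Kit (-1.88, 0.54 and 0.031), Ccnd3 (-0.41, 0.21 and 0.04) and Cd44 (-0.74, 0.6 and 0.048). The others did not pass, from Myb (-1.02, adjusted p = 0.69) to Hba-a2 (1.48, 0.83).

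Mitosis had the lowest list p at this step (33 of 45 fell and 1 rose, 38 and 1 adjusted over the list alone, median log2 fold -1.11, adjusted p = 2.4e-20 and 0.48 estimated). Mitophagy and autophagy (17 of 34 rose, 18 adjusted over the list alone, median 0.93, adjusted p = 1.6e-10 and 0.41 estimated) rose. In all, 1082 genes rose and 531 fell (1752 and 1328 with the block; 118 falls without orthochromatic library 3). Under plain totals 524 rose and 3047 fell, and without the libraries numbered 3 the counts were 154 and 0.

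Over the whole mouse course 2633 genes rose and 3129 fell, against 850 and 7152 under plain totals and 909 falls without the libraries numbered 3 (2062 without orthochromatic library 2 alone). Xpo7 rose 868-fold, Tcp11l2 from 4.42 ± 4.09 to 2644 ± 677 CPM, Tmcc2 from 146 ± 13.4 to 31060 ± 3130, the lysosomal protease gene Lgmn from 0.259 ± 0.272 to 37.4 ± 1.05, Bpgm from 56.1 ± 8.8 to 7350 ± 1196 and Tbcel from 24.1 ± 0.514 to 3133 ± 862. Zfp874a rose from 1.84 ± 0.384 to 239 ± 110 CPM, Sowaha from 17.6 ± 2.06 to 2186 ± 638, the survival gene Bcl2l1 from 35.2 ± 3.93 to 4089 ± 271, Hbq1a from 0.219 ± 0.125 to 25.9 ± 6.83, Prokr1 from 3.77 ± 0.344 to 351 ± 81.4 and Khnyn from 4.46 ± 1.58 to 400 ± 122 (adjusted p of these 12 from 9.3e-08 to 3.1e-05). Falling most were Eng (43.3 ± 9.14 to 0.911 ± 1.1 CPM, adjusted p = 0.0054), Hmgn1 (33.9 ± 26.1 to 1.17 ± 0.579), Pebp1 (30.9 ± 28.6 to 1.19 ± 1.03), Ext2 (25 ± 6.4 to 0.974 ± 1.59), the red cell pyruvate kinase gene Pklr (193 ± 19.8 to 8.38 ± 8.37, adjusted p = 0.0035) and Aldh1a7 (55.4 ± 2.74 to 2.37 ± 1.69). After them came Atic (51.4 ± 9.78 to 2.18 ± 2.66 CPM), C1qbp (62.4 ± 14 to 2.72 ± 2.83), Hspe1 (22.9 ± 11.8 to 1.01 ± 0.718), Utp20 (26.4 ± 3.67 to 1.14 ± 1.2), Stat5a (24.3 ± 5.29 to 1.07 ± 1.1) and Gatm (66 ± 1.44 to 3.09 ± 2.55), the 12 falls with adjusted p from 0.00054 to 0.025. Of these only Hmgn1, Pklr, Aldh1a7 and Gatm passed with fewer libraries, without those numbered 3.

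Of the always-named mouse genes, Beta-s (log2 fold 4.88, adjusted p = 1.3e-06), Cdkn1b (4.79, 8.4e-05), Bnip3l (4.62, 0.00087), Alas2 (4.39, 3.3e-07), Hbb-b2 (4.38, 5.5e-06), Hbb-b1 (3.73, 0.0014), Foxo3 (3.27, 1.5e-07), Slc4a1 (3.16, 7.1e-07) and E2f2 (2.83, 8.5e-07) rose. So did Hba-a1 (log2 fold 7.15, adjusted p = 0.0061), Tfrc (2, 0.00033) and Epor (1.63, 5e-05). Klf1 (1.31, adjusted p = 6.2e-05) and Gata1 (0.97, adjusted p = 4e-04) rose, with the opposite sign under plain totals (-0.28 and -0.62). Bcl11a fell (-4.18, adjusted p = 0.0049). Myc (log2 fold -3.28, adjusted p = 0.018), Cd44 (-2.61, 0.0089) and Ccnd3 (-1.17, 0.00072) fell, but not without the libraries numbered 3 (adjusted p = 0.11, 0.083 and 0.057). Itga4 (log2 fold 0.76, adjusted p = 0.052 without and 0.00023 with the block), Kit (-3.35, 0.097 and 0.00016) and Myb (-1.73, 0.21 and 0.012) passed with the block only; Gata2 (-0.9, 0.63) and Hba-a2 (2.9, 0.37) did not pass.

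Erythroid and clearance lists rose over the mouse course. Transporters and blood groups (19 of 24 rose and 1 fell, median log2 fold 2.05, adjusted p = 1.4e-08 and 0.48 estimated) held Art4 (4.09), Slc43a1 (2.83) and Slc16a1 (2.81). Abcc4 fell (-0.81). Membrane skeleton (13 of 18 rose, median 1.96, adjusted p = 7.1e-08 and 0.41 estimated) held Epb4.1 (4.69), Epb4.2 (3.48) and Tmod1 (3.27). Ubiquitin conjugation (26 of 49 rose and 3 fell, median 0.9, plain -0.73, adjusted p = 3.7e-07 and 0.54 estimated) held Ube2h (6.26), Fbxo30 (5.55) and Ube2o (5.41). Otub1 fell (-0.5). Mitophagy and autophagy (22 of 34 rose and 6 fell, 23 and 6 adjusted over the list alone, median 1.78, adjusted p = 2.3e-06 and 0.48 estimated) held Ulk1 (4.54) and Atg4a (4.3). Lamp2 fell (-0.61). Heme synthesis (12 of 15 rose and 1 fell, median 1.71, adjusted p = 2.9e-06 and 0.51 estimated) held the ferrochelatase gene Fech (3.21) and Tspo2 (3.12). Tmem14c fell (-0.69). Erythroid transcription factors (22 of 30 rose and 8 fell, median 1.18, plain -0.41, adjusted p = 7.5e-06 and 0.48 estimated) held Trim10 (4.34). Globins (7 of 10 rose, 8 adjusted over the list alone, median 3.74, adjusted p = 3.3e-05 and 0.41 estimated) shifted up. So did antioxidant enzymes (14 of 26 rose and 4 fell, median 0.82, plain -0.79, adjusted p = 0.011 and 0.48 estimated) with the catalase gene Cat (5.53), Gpx1 (3.46) and Txnrd2 (2.85) against Car1 (-2.61). G1 cyclins and CDK inhibitors (14 of 21 rose and 4 fell, median 1.18, plain -0.45, adjusted p = 0.017 and 0.6 estimated) with Ccng2 (5.66) and Gadd45a (4.39) against Cdk4 (-3.66) followed. Mitosis (18 of 45 rose, 15 adjusted over the list alone, median 0.53, adjusted p = 0.0086, 0.1 with the block and 0.98 estimated) held the securin gene Pttg1 (4.13), Cdc25b (1.94) and Cit (1.54); under plain totals 37 of them fell (median -1.05).

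Ribosome biogenesis fell over the mouse course (39 of 47 fell and 2 rose, 41 and 2 adjusted over the list alone, median log2 fold -2.7, adjusted p = 2.9e-07 and 0.54 estimated), with Nhp2 (-4.35) and Pes1 (-3.91). Sbds rose (1.26, plain -0.34). Ribosomal proteins (13 of 79 fell, 8 adjusted over the list alone, median -1.35, adjusted p = 0.064) passed with the block (73 fell, adjusted p = 3.1e-10) and without the libraries numbered 3 (19 fell and 1 rose, median -1.13, adjusted p = 2.3e-07); Rpl32 (-2.41), Rps20 (-2.32) and Rpl22 (-1.95) fell most. Oxidative phosphorylation (25 of 64 fell and 7 rose, 12 rose with the block, median -0.31, adjusted p = 0.064, 0.021 with the block) held Ndufb5 (-2.64), Ndufb2 (-1.5) and Ndufc2 (-1.47). Ndufb9 rose (0.96, plain -0.64). DNA replication (9 of 45 fell and 2 rose, 5 and 1 adjusted over the list alone, 18 and 4 with the block, median -0.45, adjusted p = 0.21) held Gins2 (-1.14), Dut (-1.08) and Gins1 (-1.06). Rrm2 rose (0.82, plain -0.78). Translation initiation factors (6 of 42 rose and 18 fell, 11 and 24 with the block, median -0.47, adjusted p = 0.29) held Ppp1r15a (4.94), Eif5 (4.56) and Eif2ak1 (3.34). Eif2b3 fell (-2.64). Iron uptake and handling (8 of 21 rose and 5 fell, median 0.27, plain -1.32, adjusted p = 0.42, 0.043 with the block) held Slc25a37 (3.63) and Iscu (3.4). Aco1 fell (-2.33). Erythropoietin and KIT signalling (8 of 20 rose and 2 fell, 5 fell with the block, median -0.08, 0.1 with RLE, but mean 0.81, adjusted p = 0.16) held Pim1 (4.55) and Pim2 (3.64). Gab1 fell (-1.64). Sort markers (2 of 4 rose and 1 fell, 3 and 1 adjusted over the list alone, median 1.82, adjusted p = 0.17) passed with the block (adjusted p = 0.031).

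Other mouse lists did not shift as a whole. Glycolysis (3 of 20 rose and 4 fell, 9 fell with the block, median log2 fold -0.7, adjusted p = 0.89) held Bpgm (7.03), against Pklr (-4.5) and Tpi1 (-2.45); proteasome (9 of 43 rose and 5 fell, 15 and 11 with the block, median 0.1, plain -1.52, adjusted p = 0.48) held Psme3 (3.77), Psmf1 (1.62) and Psmd10 (1.53, plain -0.08). Psmd3 fell (-0.99). Splicing factors (8 of 54 rose and 12 fell, 18 and 19 with the block, median -0.09, 0.05 with RLE, adjusted p = 0.91) held Snrpa (-3.4) and Prpf19 (-2.78). Rbm39 rose (1.44, plain -0.19). Histone and chromatin modifiers (10 of 45 rose and 8 fell, 10 and 6 adjusted over the list alone, 15 and 17 with the block, median -0.11, 0.03 with RLE, and mean -0.23, though the test pointed up, adjusted p = 0.57) held Ezh1 (4.54), against Prmt5 (-2.79) and Ehmt2 (-2.42). Nuclear condensation and enucleation (13 of 33 rose and 10 fell, 14 and 10 adjusted over the list alone, median 0.18, plain -1.37, adjusted p = 0.36) held Trim58 (5.33), Top1 (2.18) and Hdac6 (2.16). Apoptosis regulators (6 of 27 rose and 8 fell, median -0.12, 0.02 with RLE, adjusted p = 0.88) held Trp53inp1 (3.29) and Bbc3 (3.21). Bid fell (-3.04). Cholesterol synthesis (2 of 21 rose and 4 fell, 10 fell with the block, median -0.73, adjusted p = 0.23) held Fdft1 (1.6). Adhesion molecules (3 of 18 rose and 3 fell, 3 and 1 adjusted over the list alone, 5 and 3 with the block, median 0.43, plain -1.14, adjusted p = 0.48) held Cd36 (5.8), Cd24a (2.17) and Cd82 (1.11, plain -0.46). Itgb1 fell (-0.38).

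Mouse progenitor genes (2 of 25 rose and 3 fell, 2 and 2 adjusted over the list alone, 4 and 7 with the block, median log2 fold -0.07, 0.1 with RLE, adjusted p = 0.95) held Lyl1 (2.62) and Runx1 (1.78). Granulocyte and monocyte markers (0 of 23 rose and 0 fell, 2 rose with the block, median 0.6, plain -0.91, adjusted p = 0.48) rose without the libraries numbered 1 (16 of them, median 3.08, adjusted p = 0.00034). Macrophage markers (1 of 8 rose and 1 fell, 2 rose with the block, median 0.06, plain -1.45, adjusted p = 0.5) held Ctsb (3.06), and megakaryocyte and platelet markers (3 of 15 rose, 7 rose and 2 fell with the block, median 0.85, plain -0.69, adjusted p = 0.3) held Itga2b (3.73) and Vwf (1.32, plain -0.27). Lymphocyte markers (0 of 14 rose and 0 fell, 1 and 1 with the block, median -0.06, 0.09 with RLE, though the test pointed up, adjusted p = 0.77) and mast cell, basophil and eosinophil markers (1 of 13 rose and 2 fell, median -0.41, adjusted p = 0.94), with Il1rl1 (-1.78), stayed mixed. Adjusted over the list alone, counts of the mouse lists over the whole course were otherwise the same.

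Across all stages at once, 11027 of 12860 human genes (85.7 percent) and 6073 of 11120 mouse genes (54.6 percent; 1595 without the libraries numbered 3) differed between at least some stages in the edgeR F-test (n = 3 per stage).

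The species differed over the whole course in most always-named genes. CD44 went up in human and down in the mouse (log2 fold 2.64 and -2.55, difference 5.19, adjusted p = 1.7e-06), and ITGA4 down in human only (-3.04 and 0.82, difference -3.86, adjusted p = 3.1e-05; n = 3 per stage and species). Per the labels human sorts used band 3 (SLC4A1) and ITGA4 and mouse sorts CD44. So these 3 genes are tied to the gates, and like-named stages may not match. Rising further in human were E2F2 (difference 4.5, adjusted p = 2.5e-06), FOXO3 (3.41, 6e-09), SLC4A1 (2.3, 2.6e-06) and KLF1 (1.61, 1.6e-05). So were ALAS2 (1.22, 0.0012) and GATA1 (0.79, 0.0065), but GATA1 fell in both under plain totals. E2F2 and SLC4A1 started lower. BCL11A fell less in human (-1.51 and -4.07, difference 2.56, adjusted p = 0.014), and CCND3 fell in the mouse only (0.31 and -1.11, 1.42, 8e-04). MYB (difference -5.38, adjusted p = 0.00086) and KIT (-3.73, 0.02) had lower log2 folds in human, while XPO7 (-3.31, 2.8e-05) and TFRC (-1.47, 0.0015) rose less. KIT turned to 0.8 without mouse orthochromatic library 1. BNIP3L (0.24, adjusted p = 0.79), CDKN1B (-0.38, 0.55), EPOR (0.27, 0.34) and MYC (-0.91, 0.42) did not pass, and GATA2 did with the block only (2.32, 0.12 without and 0.00027 with it).

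DNA replication genes had lower log2 folds in human over the whole course (37 of 45 smaller and 2 larger in human, 38 and 2 adjusted over the list alone, median difference -2.49, adjusted p = 1.4e-08 and 1 estimated). Mitophagy and autophagy genes rose further in human (19 of 34 larger and 4 smaller, 21 and 4 adjusted over the list alone, median 1.4, adjusted p = 0.013 and 1 estimated). Mitosis genes were lower in human (19 of 44 smaller and 1 larger, 18 and 1 adjusted over the list alone, median -0.96, adjusted p = 0.041, 0.096 with the block and 1 estimated). Neither of the last pair passed without the mouse libraries numbered 1 (adjusted p = 0.19 each). In all, 2685 of 8580 genes had a higher and 2258 a lower log2 fold in human.

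At the last step, from polychromatic to orthochromatic, the species differed in the same cell cycle lists. DNA replication (36 of 45 smaller in human and 0 larger, 38 and 0 adjusted over the list alone, median difference -2.24, adjusted p = 1.4e-18 and 1 estimated) fell in human only. Mitosis fell further in human (18 of 44 smaller and 1 larger, 23 and 1 adjusted over the list alone, 29 smaller with the block, median -1.1, adjusted p = 7.1e-05 and 1 estimated), while ribosome biogenesis was higher (11 of 47 larger and 1 smaller, 10 and 0 adjusted over the list alone, 19 and 1 with the block, median 0.65, adjusted p = 0.013 and 1 estimated). ITGA4 (difference -2.68, adjusted p = 0.0025), TFRC (-1.85, 0.00048), CCND3 (-1.5, 0.0011) and XPO7 (-1.43, 0.044) changed less or further down in human; CD44 (1.82, 0.036), KLF1 (0.9, 0.0088) and GATA1 (0.75, 0.017) had a higher log2 fold (n = 3 per stage and species). KIT (3.41, adjusted p = 0.063 without and 0.00022 with the block) and BCL11A (-2.06, 0.067 and 0.0074) passed with the block only. The others did not pass, from CDKN1B (-0.45, adjusted p = 0.54) to MYB (1.46, 0.39). In all, 1361 genes were larger and 1575 smaller in human (2392 and 2310 with the block).

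Genes that changed in both species mostly went the same way. Over the whole course 1236 of 8577 genes rose in both (750.4 expected from independent calls; Fisher exact p = 3.3e-139, odds ratio 3.67), 1589 fell in both (1161 expected; Fisher exact p = 6.1e-91, odds ratio 2.62) and 1037 went opposite ways (1867 expected). Log2 folds correlated across genes at a Pearson r of 0.421, with genes that are not independent replicates. At the last step 426 rose in both (247.7 expected; Fisher exact p = 3.6e-42, odds ratio 2.76), 243 fell in both (144.3 expected; Fisher exact p = 1.4e-22, odds ratio 2.59) and 200 went opposite ways (398.6 expected), with a Pearson r of 0.148.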

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

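The genes and lists here were taken by a fixed rule from the species difference. Over the whole course, from proerythroblast to orthochromatic, 6 genes rose in human and rose less or went down in the mouse. The human minus mouse log2 fold was 9.69 for TRIM2 (adjusted p = 1.3e-11; log2 fold 6.73 in human and -2.96 in the mouse), 9.28 for MAST3 (2.4e-07; 6.47 and -2.81), 8.97 for TRPV2 (6.4e-11; 7.23 and -1.74) and 8.68 for TNS1 (8.9e-12; 8.13 and -0.55). It was 8.45 for RUNDC3A (adjusted p = 2.2e-10; 13.24 and 4.79) and 7.14 for ACP5 (5.7e-07; 5.41 and -1.73). The other way went RRAGD (-8, adjusted p = 9.5e-08; -4.81 and 3.19), IBTK (-7.61, 4.1e-12; -3.19 and 4.42), IFNAR2 (-7.53, 3.8e-12; -4.9 and 2.62), NSMAF (-7.35, 9.6e-12; -5.23 and 2.12) and MRM1 (-7.15, 6.9e-11; -3.91 and 3.24). CD36, a fatty acid receptor, also did (-7.1, adjusted p = 4.8e-10), going from 1164 to 491 CPM in human and from 92.4 to 5335 CPM in the mouse.

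From polychromatic to orthochromatic the largest positive differences were CBFA2T2 (6, adjusted p = 2.4e-08), the clock gene PER1 (4.56, 1.8e-05), ACP5 (4.43, 0.00029), SORD (4.35, 3.1e-06), the linker histone gene HIST1H1C (4.1, 2.9e-06) and SLC20A2 (3.83, 1.1e-05). Among the largest negative ones were CD36 (-3.96, adjusted p = 4.3e-06), RELN (-3.7, 1.1e-05), the S-phase cyclin gene CCNE2 (-3.7, 0.00016) and the replication genes EXO1 (-3.41, 6.9e-05) and CDT1 (-3.41, 4.8e-05).

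Over the whole course the lists with a species difference were DNA replication (adjusted p = 1.4e-08), mitophagy and autophagy (adjusted p = 0.013) and mitosis (adjusted p = 0.041), each with an adjusted p of 1 with an estimated correlation. Mitosis did not pass with the block (adjusted p = 0.096), and neither it nor mitophagy passed without the mouse libraries numbered 1 (0.19 each). At the last step they were DNA replication (adjusted p = 1.4e-18), mitosis (adjusted p = 7.1e-05) and ribosome biogenesis (adjusted p = 0.013), again each 1 with an estimated correlation. A human row that names no gene held at most 0.002298 percent of a library's counts and was not analysed. Sorting gates, cell sources and TMM factors differ too, so a species difference here is also one of culture against bone marrow.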

How the results depend on the processing

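Plain totals, leaving out libraries numbered 1 or 3 and permuting within number were chosen after seeing the data, others beforehand. Permuted within library number, mouse genes detected at equal depth differed between stages (exact permutation p = 0.0069, 0.22 otherwise). For human orthochromatic against proerythroblast, where library numbers do not pair, the block changed the calls of TFRC (adjusted p = 0.061 to 0.0096) and oxidative phosphorylation (0.039 to 0.063). Of lists not given in the report for a step, it added lymphocyte markers (adjusted p = 0.0052) at the first human step and splicing factors (0.045) at the last. It ended the calls of heme synthesis (adjusted p = 0.037 to 0.074) and glycolysis (0.048 to 0.078) from late basophilic to polychromatic, and of ribosome biogenesis (0.045 to 0.063) and ribosomal proteins (0.048 to 0.052) at the last human step. In the mouse it added sort markers (0.019), iron handling (0.019) and granulocyte markers (0.042) from proerythroblast to basophilic, membrane skeleton (0.02) and granulocyte markers (0.015) from basophilic to polychromatic, and granulocyte markers (0.0032) at the last step. Without libraries numbered 1 granulocyte markers passed too at the first (8.4e-07) and last (3e-10) mouse step, on at most 0.019 percent of a library's counts. Beyond these and the report it changed no call of a named gene or list.

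From human proerythroblast to early basophilic, 21 genes rose and 3 fell. The counts were 113 and 68 with DESeq2, 150 and 136 with the block, 2 and 1 with only the 6 libraries of these stages, and 69 and 566 with limma on log2 RPKM. Without a single library, rises went to 1 (proerythroblast 1), 4 (proerythroblast 3), 5 (early basophilic 1), 10 (proerythroblast 2), 12 (early basophilic 2) and 28 at most, and falls to 0 (proerythroblast 1 or 3, early basophilic 1 or 2), 1 (proerythroblast 2) and 3 at most. With only those 6 libraries PAQR9 (adjusted p = 0.1), TNS1 (0.069), SLC6A9 (0.1), HMGCS1 (0.1), SLC4A1 (0.069) and CCND3 (0.1) lost their calls. HBM lost its call with 1 library left out (0.07).

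From early to late basophilic, 319 rose and 257 fell. Rises were 206 with RLE, 570 with DESeq2, 1273 with the block, 187 under plain totals and 517 without libraries numbered 1. Falls were 754 with DESeq2, 1103 with the block, 703 with only the 6 libraries, 2271 with limma, 608 under plain totals and 446 without libraries numbered 1. Without a single library, rises went to 11 (early basophilic 3), 19 (late basophilic 1), 31 (early basophilic 2), 146 (late basophilic 3), 201 (late basophilic 2) and 267 at most. Falls went to 14 (early basophilic 3), 40 (late basophilic 1), 62 (early basophilic 2), 66 (late basophilic 3), 93 (late basophilic 2) and 126 (early basophilic 1).

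From late basophilic to polychromatic, 3363 rose and 4091 fell. Limma gave 1161 and 7900 and plain totals 1526 and 7198. From polychromatic to orthochromatic, 3585 rose and 3607 fell. Limma gave 569 and 7225 and plain totals 1305 and 7131. From proerythroblast to orthochromatic, 4512 rose and 5574 fell. Limma gave 1023 and 10403 and plain totals 1683 and 9526. Leaving out 1 library lost ITGA4 (highest adjusted p = 0.11), GATA1, TFRC, HBD and CCND3 (0.17) from late basophilic to polychromatic, and GATA2 at the later steps.

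From mouse proerythroblast to basophilic, 2266 rose and 2113 fell. Rises were 1016 with limma, 962 under plain totals and 911 without libraries numbered 3. Falls were 3921 with the block, 1331 with only the 6 libraries, 6164 with limma, 4887 under plain totals, 4314 without libraries numbered 1 and 20 without those numbered 3. Without a single library, falls went to 925 (basophilic 2), 936 (basophilic 3), 1321 (proerythroblast 3), 1324 (proerythroblast 2), 1362 (proerythroblast 1) and 3121 at most.

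From mouse basophilic to polychromatic, 85 rose and 16 fell. Rises were 157 with RLE, 493 with DESeq2, 522 with the block, 0 with only the 6 libraries, 44 with limma, 36 under plain totals, 1442 without libraries numbered 1 and 0 without those numbered 3. Falls were 9 with no filter, 223 with DESeq2, 322 with the block, 0 with only the 6 libraries, 4 under plain totals, 1336 without libraries numbered 1 and 0 without those numbered 3. Without a single library, rises went to 0 (basophilic 2), 1 (basophilic 3 or polychromatic 2), 28 (polychromatic 3), 39 (polychromatic 1) and 375 (basophilic 1), and falls to 0 (basophilic 2 or polychromatic 2), 1 (basophilic 3), 2 (polychromatic 3), 8 (polychromatic 1) and 159 (basophilic 1).

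From mouse polychromatic to orthochromatic, 1082 rose and 531 fell. Rises were 1752 with the block, 583 with limma, 524 under plain totals, 2441 without libraries numbered 1 and 154 without those numbered 3. Falls were 1328, 2885, 3047, 1950 and 0 in that order. Without a single library, falls went to 118 (orthochromatic 3), 161 (orthochromatic 2), 246 (polychromatic 3), 281 (polychromatic 2) and 673 at most. From proerythroblast to orthochromatic, 2633 rose and 3129 fell. Limma gave 886 and 7544, plain totals 850 and 7152, and falls without libraries numbered 3 were 909. Without a single library, falls went to 2062 (orthochromatic 2), 2083 (orthochromatic 3) and 3005 at most. The any-difference count, 6073, was 1595 without libraries numbered 3. Of the genes named with the lists over the mouse course, Tmem14c, Abcc4, Itgb1, Lamp2, Gins2, Dut, Rrm2, Ehmt2, Nhp2, Pes1, Ndufb5, Ndufb2, Otub1, Rbm39 and Bid lost their calls without libraries numbered 3 (adjusted p from 0.057 to 0.51). Rps20 lost its call without those numbered 1 (adjusted p = 0.088).

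Some called genes changed sign with limma on log2 RPKM. In human these were GATA1 (-0.54), EPOR (-0.01) and TFRC (-0.33) from late basophilic to polychromatic, and CD44 (-0.44), GATA1 (-0.9), KLF1 (-0.77) and CDKN1B (-0.41) from polychromatic to orthochromatic. Over the whole human course they were CD44 (-0.4), GATA1 (-1.27), GATA2 (-0.92), KLF1 (-0.12), EPOR (-1.11), HBD (-0.01), SELPLG (-0.4), RFC3 (-1.49), CDC25B (-0.94), RPS27L (-0.64), SBDS (-1.51), ATP5E (-1.09), CYBB (-0.83) and SRGN (-1.29). Over the mouse course they were Gata1 (-0.62), Klf1 (-0.28), Cd82 (-0.48), Rrm2 (-0.78), Cit (-0.05), Sbds (-0.33), Ndufb9 (-0.63), Psmd10 (-0.06), Rbm39 (-0.22) and Vwf (-0.24).

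Under plain totals the sign changed for human GATA1 (-0.27) and TFRC (-0.06) from late basophilic to polychromatic and for GATA1 (-0.4) and KLF1 (-0.27) from polychromatic to orthochromatic. Over the whole human course it changed for GATA1 (-0.42), GATA2 (-0.6), EPOR (-0.26), RFC3 (-0.71), CDC25B (-0.21), SBDS (-0.78), ATP5E (-0.23), CYBB (-0.76) and SRGN (-0.32). Over the mouse course it changed for Gata1 (-0.62), Klf1 (-0.28), Cd82 (-0.46), Rrm2 (-0.78), Cit (-0.03), Sbds (-0.34), Ndufb9 (-0.64), Psmd10 (-0.08), Rbm39 (-0.19) and Vwf (-0.27). Of lists over the whole course, human progenitor genes lost their call (adjusted p = 0.15). Human splicing factors (0.00063), mouse splicing factors (0.023), DNA replication (0.0035) and oxidative phosphorylation (0.00029) were called down. Called up against all other genes were human granulocyte (adjusted p = 0.0027) and macrophage markers (0.017), mouse granulocyte (0.00031), platelet (0.034) and lymphocyte markers (0.034), and mouse KIT signalling (0.033). With RLE, human oxidative phosphorylation (0.074) and the species difference of mitosis (0.053) lost their calls and mouse ribosomal proteins (0.018) gained one. List medians changed sign with limma for human proteasome from late basophilic to polychromatic (-0.66), human ribosome biogenesis from polychromatic to orthochromatic (-0.57) and mitosis over the mouse course (-1.05, and -1.05 under plain totals).

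The species difference of KIT over the whole course (-3.73) was 0.14 without mouse libraries numbered 1 and ran from -4.45 (without mouse proerythroblast 1) to 0.8 (without mouse orthochromatic 1). At the last step 1361 genes were larger in human; the count was 2392 with the block, 2134 with limma-voom and library weights and 883 under plain totals. Leaving globin genes out of the library sizes changed no call of a named gene.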

Other observations

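These families were chosen after seeing the data; 20 such tests were adjusted together and part of those that passed is given. Histone genes rose over the whole course in both species: 28 of 41 in human (19 under plain totals, median log2 fold 3.41 and 1.23, adjusted p = 8.3e-05, and 0.57 with an estimated correlation) and 45 of 57 in the mouse (9 under plain totals, median 2.4 and 0.86, adjusted p = 2e-09, and 0.54 with an estimated correlation). Counts are uncertain between near-identical copies.

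All tests of this pattern were chosen only after seeing the result. Granulocyte and monocyte genes are highest in mouse libraries numbered 1: 23 of 24, all but Cd14, at all 4 stages. The median log2 ratio was 6.01 for this list and 0.96, 1.36, 2.17 and 2.53 for macrophage, platelet, lymphocyte and mast cell markers. All were raised, but not alike as a lower share of erythroblasts would raise them. Depth alone is not the source (lowest ratio of the shares 22.65). Granulocytes are a likely source, a hypothesis protein markers could test.

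All tests here but that on pseudogenes were chosen after seeing the result. Ribosomal protein genes are high in mouse libraries numbered 3, by a median log2 ratio of 3.88 over 76 genes. Against the deeper libraries 1 it was at least 3.37 at each stage, so depth is not the source. Of the 76, 55 shifted by over 2 at all stages and 6 by under 0.5 (SD over genes 2.32). Not all rose alike, and higher expression of most is undecided. Shared reads with pseudogenes could not be decided, with too few such genes (Fisher exact p = 1). The cause stays open and could lie in library preparation or counting.

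All tests of this pattern were chosen only after seeing the result. Under plain totals the median human gene changed by -2.53 between proerythroblast and orthochromatic, from means of logs, against -0.35 with TMM. Without globin genes it changed by -2.21, without the 50 genes with most counts by -1.88 and without 10 times as many by -1.18. A growing share of globin transcripts may account for a small part only, and abundant genes together for more. No spike-in was used here, so whether total RNA per cell fell is open.

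Splits of the libraries into other groups were used for chance. With 3 against 3 libraries only 1 of 10 splits is the real one, which is too few to exclude chance in any comparison of 2 stages. In human these called 24, 576, 7454, 7192 and 10086 genes (highest other 0, 0, 0, 11 and 0), and in the mouse 4379, 101, 1613 and 5762 (highest other 0). Among 100 regroupings over all stages only the real one (1) reached 11027 in human (highest other 8084) and 6073 in the mouse (4159), which excludes chance at that share. For the species difference 3 of 100 reached 4943 over the whole course (highest other 6279), and 6 of 100 reached 2936 at the last step (highest other 3950). The others among these, 2 and 5, keep the real human stages and so hold the human change. With human regrouped the highest other was 2874 and 822, and with both species regrouped (80 splits) 0 and 2, but these lack the stage changes too. Whether chance is excluded stays open for the species difference.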
